A study of Mus musculus with 9 samples.

How the data were processed

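Total RNA from whole mouse corneas was prepared with Trizol, amplified with the Ambion WT Expression kit, labelled with biotin using the Affymetrix WT Terminal Labeling kit and hybridised to single-colour arrays, per the labels. The series holds 9 arrays in 3 groups of 3: Dstn corn1 mutant, rescued (Dstn corn1 mutant in which Srf was ablated genetically in the epithelium of the cornea) and WT. The deposited values are log2 intensities that the authors normalised between arrays; the normalisation method and software are not given in the sources used here. Base 2 was inferred from the range of the values (2.14 to 14.3), whose antilog to base 2, and not to base 10 or e, lies in the range of a 16-bit scanner. Intensities are relative, and the number of arrays per group limits the precision.

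The value table has 41345 rows. The platform annotation gives exactly 1 gene symbol for 23521 of them, several symbols for 1814 and does not list 16010, among them 190 control rows. Rows with exactly 1 symbol were used, and for the 1082 genes with more than 1 row the row with the highest mean over all arrays stood for the gene, which left 22180 genes; no filter on intensity was applied. A reference gene table was used for symbols (22139 found) and for gene order; the genome build behind the array annotation is not given in the sources used here.

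The 3 comparisons (mutant with WT, rescued with mutant, rescued with WT) were fitted with limma (version 3.58.1, R 4.3.3) over all 9 arrays (lmFit, contrasts, eBayes), and an F test covered the 3 groups. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. SEs are the moderated SEs of limma. Tests were two-sided. Folds are ratios of measured intensities; those with a lower group mean below the median of all rows (6.77) are given as lower bounds, which assumes that background adds to the signal. The fit was checked on simulated data of the same size, with 50 genes changed at each of 0.5, 1, 2 and 3 on the log2 scale. Of these, 70%, 96%, 100% and 100% were recovered, with 6 false calls among the unchanged genes. Far fewer genes changed there than were called in the data, so recovery in the data may differ.

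The 31 gene lists, the named-gene rule, the tests and most alternatives were fixed before the data were examined. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison; camera with an estimated correlation and fry were alternatives. Some genes stand in more than 1 list. The rule named Dstn and Srf, the 10 genes with the largest log2 increase and the 10 with the largest decrease in each comparison among called genes whose groups did not overlap (without model or clone symbols, olfactory and vomeronasal receptors, microRNA and small nucleolar RNA genes), and up to 4 members of each list with the largest absolute change. A gene named in 1 comparison could be given values in the others. Krt12, Pax6, Klf4, Slc5a1, Adamtsl4, Cdkn2b, Cdr2 and Bmp7, and Krt14 in the comparison of mutant with WT, were chosen after their values were seen.

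The share reversed of a gene is minus the rescued minus mutant difference divided by the mutant minus WT difference, in percent, on the log2 scale unless the linear scale is named. Intervals of a difference between 2 lists are from 10000 bootstrap resamples of their genes. Overlaps were set against the product of the list sizes over the genes tested, and against 100 simulations (seed 20) that kept the shared arrays, without group effects or with rescued equal to mutant.

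The alternatives were quantile normalisation, centring on the array median, filters at the median and the 25th percentile of intensity, the mean of all rows of a gene, all rows, trend and robust options, the 6 arrays of a comparison alone, array weights, the replicate number as a block, an unmoderated equal-variance test per gene, an adjusted p under 0.01, a 2-fold minimum, and leaving out each array. A covariate for Y-linked expression was added after seeing the data. The replicate numbers do not pair the arrays, so the block was used as an alternative. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Raw scanner files were not used here.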

Results

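Gene expression was measured in whole mouse corneas of 3 genotypes with single-colour expression arrays. The mutant group carried the corn1 allele of Dstn, the gene for destrin, an actin depolymerising factor. The rescued group carried the same Dstn mutation together with genetic ablation of Srf, the gene for the transcription factor serum response factor, from the corneal epithelium. The third group was wild type (WT). Each group had 3 biological replicates, and each replicate was a pool of 10 corneas from 5 mice. All mice received doxycycline from postnatal day 28 to postnatal day 58 and were 58 days old at collection, and their strain background was mixed. The values are log2 intensities, normalised by the authors with a method not given in the sources used here, and base 2 was inferred from their range. Background control probe sets had mean log2 intensities from 2.49 to 9.49, so that no single level separates signal from background. Where the lower of the groups compared lay below 6.77, the median of all rows, signal above background was not shown and the fold is given as a lower bound, with the words at least. The median log2 intensity over all rows lay between 6.75 and 6.78 on the 9 arrays, and the number of arrays per group limits the precision of every comparison. Pearson correlations across all 41345 rows, control rows included, were 0.990 to 0.993 between arrays of 1 group. Between mutant and WT arrays they were 0.971 to 0.974. They were 0.981 to 0.988 between mutant and rescued arrays and 0.982 to 0.986 between rescued and WT arrays. Rows are not independent replicates. On the first principal component, which held 68.0% of the variance, the rescued arrays lay between −8.87 and 6.79, with the mutant arrays between −39.0 and −34.8 and the WT arrays between 39.4 and 39.8. Among 22180 genes tested, 6524 differed among the 3 groups at an adjusted p under 0.05 (limma moderated F test).

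Dstn (probe set 17377013) had a log2 intensity of 12.57 ± 0.02 (SD, n = 3) in WT, 5.63 ± 0.15 in mutant and 5.62 ± 0.01 in rescued corneas. Dstn was at least 123-fold lower in mutant than in WT corneas (log2 difference −6.95, SE 0.08, adjusted p = 5.7e-11) and at least 124-fold lower in rescued than in WT corneas. The rescued and mutant pools did not differ in Dstn beyond the replicate spread (log2 difference −0.01, SE 0.08, adjusted p = 0.96). Srf (probe set 17345465) was 2.94-fold higher in mutant than in WT corneas, with log2 intensities of 10.68 ± 0.12 and 9.13 ± 0.13 (SE of the difference 0.21, adjusted p = 0.000344). In the rescued corneas Srf was at 9.01 ± 0.51, which was 3.18-fold lower than in the mutant (adjusted p = 0.000841) and not distinguishable from WT (log2 difference −0.12, SE 0.21, adjusted p = 0.787). The 3 rescued pools had Srf log2 intensities of 9.14, 9.45 and 8.45, and all 3 lay below each mutant pool.

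**Figure D1:**
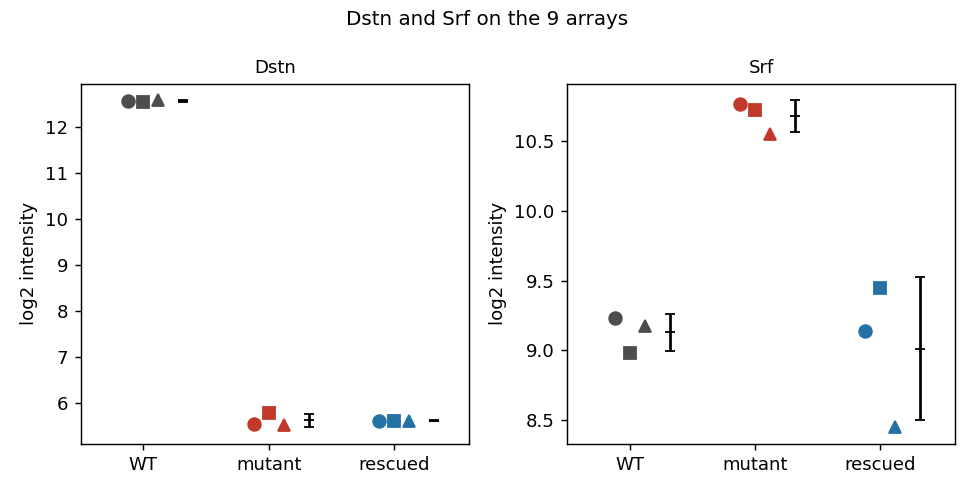
Log2 intensity (vertical axis) of Dstn (left) and Srf (right) on each array of the WT, mutant and rescued groups; symbols are the 3 replicates of a group, and the black bars give the mean ± SD. Dstn lay near 12.6 in WT and near 5.6 in both other groups, while Srf was at 10.7 in mutant and near 9 in WT and rescued corneas.

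The comparison of mutant with WT corneas asked which transcripts change in the absence of normal Dstn. Of 40 actin and contractile SRF targets 38 were higher in the mutant, as were 24 of 25 macrophage markers and 21 of 24 blood endothelial markers, and of 26 genes of corneal epithelial differentiation 13 were lower and 2 were higher. These 4 lists passed camera with a preset correlation and not with an estimated one (adjusted p = 0.145 with an estimated correlation, for each). Ppbp, the gene for a platelet chemokine, was at least 140.5-fold higher in mutant than in WT corneas (log2 difference 7.13, SE 0.31, adjusted p = 6.0e-07). Acta1, the gene for skeletal alpha-actin, was 56.6-fold higher (SE 0.23 on the log2 scale, adjusted p = 3.66e-07), and Krt17, the gene for a keratin of stressed epithelium, was 51.7-fold higher (SE 0.12, adjusted p = 9.47e-09). Necab1, the gene for a calcium-binding protein, was at least 22.6-fold lower (SE 0.06, adjusted p = 2.56e-10), and Slc34a2, the gene for a sodium-phosphate cotransporter, was 19.8-fold lower (SE 0.08, adjusted p = 3.64e-09).

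Of 22180 genes, 7004 (31.6%) passed an adjusted p of 0.05 between mutant and WT, 3355 higher and 3649 lower in the mutant, and 1116 of them differed at least 2-fold, 674 higher and 442 lower. Higher genes were 47.9% of all calls, 52.1% after quantile normalisation and 51.3% after centring on the array medians. The 3 mutant arrays all lay above or all lay below the 3 WT arrays in 44.7% of genes, against 10% by chance. Besides Ppbp, Acta1 and Krt17, the named genes with the largest measured increases were Chil4, Csn1s1, Serpinb3a, Adm, Prnd, Alox15 and Mmp3. Alox15 was 35.9-fold higher, and the 6 others, whose WT intensity lay below the median of all rows, were at least 32.4-fold higher. Adm encodes the vasodilator peptide adrenomedullin, and Mmp3 the matrix protease stromelysin-1. Besides Dstn, Necab1 and Slc34a2, the largest measured decreases were in Cyp2b19, Ces1d, Ano4, Ankrd34c, Enpep, Gldc and Ly6g6c. Gldc was 11.4-fold and Ly6g6c 11.2-fold lower, and the 5 others at least 12.2-fold. Cyp2b19 encodes a cytochrome P450 of keratinocytes, and Gldc the glycine decarboxylase of the glycine cleavage system.

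Actin and contractile targets of SRF, a list fixed before the data were examined, rose in mutant corneas. Of 40 measured members, 38 were higher and 1 was lower in the mutant, and 39 and 1 when adjusted over the list alone. The median log2 difference of the list was 1.16 (camera, adjusted p = 2.29e-23; adjusted p = 0.145 with an estimated correlation). Acta2, the gene for smooth muscle alpha-actin, was 30.1-fold higher (adjusted p = 3.66e-07), Fhl2 10.7-fold (adjusted p = 3.94e-06) and Actg2 10.5-fold (adjusted p = 2.9e-06). Among 21 immediate early targets of SRF, which include Srf itself, 14 were higher and 1 was lower, and 16 and 1 when adjusted over the list alone (camera, adjusted p = 3.02e-07; adjusted p = 0.145 with an estimated correlation). Nr4a1, Atf3 and Ankrd1 were 7.66-fold, 5.92-fold and 4.29-fold higher. Of 26 regulators of actin turnover, which include Dstn itself, 13 were higher and 3 were lower (14 and 5 when adjusted over the list alone). Diaph3, the gene for a formin, was 2.61-fold higher and Cfl2, the gene for muscle cofilin, 2.28-fold higher, while Scin, the gene for the actin-severing protein scinderin, was 4.48-fold lower. For that list the median (0.23) and the mean (−0.04) differed in sign, and so did the tests: camera gave an upward direction (adjusted p = 0.00317; adjusted p = 0.145 with an estimated correlation) and fry a downward one (adjusted p = 0.0913).

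Of 26 genes of corneal epithelial differentiation, 13 were lower and 2 were higher in the mutant, and 14 and 4 when adjusted over the list alone (camera, adjusted p = 0.00135; adjusted p = 0.145 with an estimated correlation). Dsg1a, the gene for a desmoglein, was 5.08-fold lower, Aldh1a1 4.2-fold lower and Slurp1 3.1-fold lower, whereas Cldn4, the gene for a claudin, was 2.6-fold higher. Of genes chosen after their values were seen, Krt12, the gene for the cornea-specific keratin 12, was 1.33-fold lower (log2 difference −0.42, SE 0.05, adjusted p = 0.000261) at a log2 intensity of 13.5 to 13.9, near the top of the measured range. Pax6 was 1.6-fold lower (adjusted p = 0.000181), Klf4 1.55-fold lower (adjusted p = 5.75e-05) and Krt14, a basal cell keratin gene, 2.33-fold higher (adjusted p = 2.08e-06). Among 36 stress and cornified-type epithelial genes, 22 were higher and 7 were lower, and 23 and 7 when adjusted over the list alone (camera, adjusted p = 1.55e-05; adjusted p = 0.145 with an estimated correlation). Krt16 was 14.8-fold higher (adjusted p = 3.66e-07), and Krt10, a keratin gene of cornifying epidermis, was 10-fold lower (adjusted p = 1.49e-07). Of 18 markers of conjunctiva and goblet cells, 8 were higher and 1 was lower (10 and 1 over the list alone; camera, adjusted p = 5.68e-05; adjusted p = 0.145 with an estimated correlation). The members that moved most were the keratin genes Krt18 (20-fold higher), Krt8 (19.1-fold), Krt4 (7.84-fold) and Krt19 (5.9-fold), which are expressed by simple and mucosal epithelia. Of 43 cell cycle genes, 37 were higher and 1 was lower (40 and 1 over the list alone; camera, adjusted p = 2.97e-14; adjusted p = 0.243 with an estimated correlation), among them the mitotic kinase genes Bub1 (2.09-fold) and Plk1 (2.08-fold).

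Of 25 monocyte and macrophage markers, 24 were higher and none was lower, also when adjusted over the list alone, with a median log2 difference of 1.30 (camera, adjusted p = 1.26e-12). Ly6c2 was 7.69-fold, Fcgr2b 7.31-fold and Ptprc, the gene for the pan-leukocyte protein CD45, at least 5.29-fold higher. Of 16 dendritic cell and MHC class II genes, 11 were higher and 1 was lower, also over the list alone (camera, adjusted p = 0.000109), with H2-Ab1 8.91-fold and H2-Aa at least 8.54-fold higher. Of 27 neutrophil markers, 14 were higher and 2 were lower, and 16 and 2 over the list alone (camera, adjusted p = 9.87e-06). Lcn2 (6.56-fold) and Ltf (5.33-fold), whose products also occur in epithelial secretions, were higher, and Asprv1, which keratinocytes also express, was 3.77-fold lower. Of 37 chemokines and inflammatory cytokines, 24 were higher and none was lower, and 26 and 0 over the list alone (camera, adjusted p = 5.06e-10), with Tslp, the gene for an epithelial cytokine, at least 9.52-fold and Il1b at least 6.68-fold higher. For these 4 lists the adjusted p with an estimated correlation was 0.145. Of 25 markers of T, B, NK and mast cells, 12 were higher and 1 was lower, and 13 and 1 over the list alone (camera, adjusted p = 0.000189; adjusted p = 0.243 with an estimated correlation). The mast cell protease genes Mcpt4 and Cpa3 were at least 14-fold and at least 10.3-fold higher. Of 21 interferon response genes, 6 were lower and none was higher, also over the list alone, and the list as a whole did not pass its test (camera, adjusted p = 0.201); Oasl1 was 2.21-fold lower (adjusted p = 5.97e-05).

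Of 24 blood endothelial markers, 21 were higher and 1 was lower, also over the list alone (camera, adjusted p = 2.11e-11). Emcn was at least 13.7-fold, Cdh5, the gene for VE-cadherin, at least 10.4-fold and Pecam1 5.06-fold higher. Of 9 lymphatic endothelial markers, 7 were higher, and 9 over the list alone (camera, adjusted p = 1.1e-05), with Lyve1 at least 3.47-fold higher. Of 12 pericyte and smooth muscle markers, 8 were higher and 1 was lower, also over the list alone (camera, adjusted p = 9.87e-06), with Rgs5 at least 27.9-fold and Mcam 8.44-fold higher; Acta2, Cnn1 and other members of this list are also among the SRF targets. Of 26 genes of matrix proteases and fibrosis, 17 were higher and none was lower, and 20 and 0 over the list alone (camera, adjusted p = 5.06e-10), with Plaur, the gene for the urokinase receptor, at least 15.2-fold and Tnc, the gene for tenascin C, at least 12.6-fold higher. The adjusted p with an estimated correlation was 0.145 for these 4 lists. Of 23 angiogenic and anti-angiogenic factors, 12 were higher and 2 were lower, also over the list alone (camera, adjusted p = 0.00135; adjusted p = 0.155 with an estimated correlation). Vegfa was 2.43-fold higher, and Timp1 and Timp3, which encode protease inhibitors, were at least 5.43-fold and 1.8-fold higher. Of 11 corneal endothelial genes, 7 were lower and 1 was higher, and 8 and 1 over the list alone (camera, adjusted p = 0.0221; adjusted p = 0.257 with an estimated correlation). Keratocyte and stromal matrix genes had 6 of 28 members higher and 6 lower (camera, adjusted p = 0.703), with Aspn at least 9.54-fold and Col3a1 3.23-fold higher. Epithelial adhesion and junction genes had 9 of 26 members higher and 5 lower (camera, adjusted p = 0.0602), with the claudin gene Cldn1 7.95-fold higher. Among 21 EGF receptor ligands and other epithelial growth factor genes, 7 were higher and 9 were lower (camera, adjusted p = 0.755), with Epgn, the gene for epigen, 7.14-fold higher; the median of that list was −0.13 and its mean 0.31. Over the list alone these 3 lists had 6 and 6, 10 and 5, and 8 and 9 members higher and lower.

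Lists that describe other tissue, sex and handling were measured beside these groups. Lens genes were lower in mutant corneas in 11 of 18 members, and in 12 over the list alone (camera, adjusted p = 0.000109; adjusted p = 0.291 with an estimated correlation). The median log2 difference of the list was −0.70. The mean log2 intensity of only 3 of its genes, Cryaa, Cryba1 and Crygs, was 10.8 to 11.4 in the WT pools. In the mutant pools it was 10.4, 8.54 and 8.86. Of 13 retina and pigment cell genes, 5 were lower and none was higher, and 5 and 1 over the list alone (camera, adjusted p = 0.194). Circadian clock output genes were lower in 10 of 15 members and higher in 2 (10 and 4 over the list alone; camera, adjusted p = 0.00188; adjusted p = 0.16 with an estimated correlation), with Hlf 3.48-fold, Nr1d1 2.46-fold and Dbp 2.36-fold lower. None of 4 sex-linked genes passed the test (camera, adjusted p = 0.563), but the pools differed within groups: the mean log2 intensity of 3 Y-linked genes was 5.34 and 5.15 in WT replicates 1 and 3 and between 7.16 and 9.77 in the 7 other pools, and Xist was at 6.12 in mutant replicate 2 and between 11.8 and 12.9 elsewhere. Heat shock genes were higher in 4 of 12 members, and in 5 over the list alone (camera, adjusted p = 0.0613). Of 14 skeletal muscle genes, Acta1 was higher and Ckm was at least 1.21-fold lower, also over the list alone (camera, adjusted p = 0.963). Lacrimal and meibomian gland genes had 1 higher member of 11, Ltf, also over the list alone (adjusted p = 0.678). Of 9 nerve and Schwann cell genes, 2 were higher and 2 were lower, also over the list alone (adjusted p = 0.703), and Slc4a1, the measured red blood cell gene, had a log2 difference of −0.03 (adjusted p = 0.81). The median and the mean also differed in sign for the skeletal muscle list (−0.04 and 0.34), the gland list (−0.003 and 0.20). No list was called in any of the 3 comparisons when camera estimated the correlation between genes. With fry, the contractile SRF (adjusted p = 6.15e-05), differentiation (4.8e-06), macrophage (0.000634) and blood endothelial (0.000161) lists passed between mutant and WT. Over the 3 comparisons, fry gained 12 list calls, lost 5 and reversed 2. The call of the T, B, NK and mast cell list was lost without genes below the median intensity (adjusted p = 0.491). The share of higher genes was 60.4% among the calls of at least 2-fold.

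The comparison of rescued with mutant corneas asked which of these values differ once Srf is ablated in the epithelium. Of 40 actin and contractile SRF targets 34 were lower and 1 was higher in rescued than in mutant corneas, and of 26 genes of corneal epithelial differentiation 13 were higher and 3 were lower. Both lists passed camera with a preset correlation and not with an estimated one (adjusted p = 0.296 and adjusted p = 0.0783 with an estimated correlation). Slc34a2 was 11.2-fold higher (log2 difference 3.49, SE 0.08, adjusted p = 8.02e-08), and Ly6g6c 7.78-fold higher (SE 0.10, adjusted p = 1.87e-06). Cd274, the gene for the immune checkpoint ligand PD-L1, was 5.67-fold higher (SE 0.18, adjusted p = 4.72e-05). Csn1s1, a casein gene, was at least 21.6-fold lower (log2 difference −4.43, SE 0.53, adjusted p = 0.000658), and Tagln, the gene for the smooth muscle protein transgelin, 3.94-fold lower (SE 0.18, adjusted p = 0.000184).

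In all, 2959 genes differed between rescued and mutant corneas, 1432 higher and 1527 lower in the rescued group, and 312 of them at least 2-fold, 166 higher and 146 lower. The other named genes with the largest increases were Ces1d, S100a7a, Gldc, Pbp2, Smim31, Lce3a and Anxa9, each at least 5.46-fold. Besides Csn1s1 and Tagln, those with the largest decreases included Clec2e, Prnd, Dhrs9, Nppb, Cnn1, Plaur and Pmaip1, between 3.95-fold and 5.66-fold; Nppb encodes the brain natriuretic peptide and Cnn1 the smooth muscle protein calponin. Of the 40 actin and contractile SRF targets, 34 were lower and 1 was higher in rescued than in mutant corneas, and 35 and 1 over the list alone (camera, adjusted p = 8.01e-24; adjusted p = 0.296 with an estimated correlation). Fhl2 was 3.58-fold and Actc1, the gene for cardiac alpha-actin, at least 3.4-fold lower. Of the immediate early targets, 8 of 21 were lower, 1 of them Srf, the ablated gene itself, and none was higher, and 10 and 0 over the list alone (camera, adjusted p = 0.000171; adjusted p = 0.338 with an estimated correlation), with Ankrd1 3.21-fold and Nr4a1 3-fold lower. Of the regulators of actin turnover, 9 of 26 were lower and 1 was higher (10 and 1 over the list alone; camera, adjusted p = 0.00855; adjusted p = 0.306 with an estimated correlation), and Scin was 2.78-fold higher.

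Of the 26 corneal epithelial differentiation genes, 13 were higher and 3 were lower in rescued than in mutant corneas, and 15 and 4 over the list alone (camera, adjusted p = 4.91e-06; adjusted p = 0.0783 with an estimated correlation). Dsg1a was 2.9-fold, Slurp1 2.79-fold and Muc4, a membrane mucin gene, 2.31-fold higher. Of genes chosen after their values were seen, Klf4 was 1.58-fold higher (adjusted p = 0.000226), Pax6 1.36-fold higher (adjusted p = 0.00723) and Krt12 1.31-fold higher (adjusted p = 0.00142). Of 21 interferon response genes, 8 were higher and none was lower, and 10 and 0 over the list alone (camera, adjusted p = 8.75e-08; adjusted p = 0.351 with an estimated correlation). Oasl1 was 3.14-fold and Irf7 2.42-fold higher. The pools differed: the median departure of this list from a uniform return of all genes was 0.92 and 0.94 on the log2 scale in rescued replicates 1 and 2 and 0.06 in rescued replicate 3, which stood apart. Blood endothelial markers were lower in 11 of 24 members, and in 16 over the list alone (camera, adjusted p = 3.4e-07; adjusted p = 0.306 with an estimated correlation), with Plvap 1.87-fold and Cdh5 1.72-fold lower. Lymphatic markers were lower in 4 of 9 members, and in 6 over the list alone (camera, adjusted p = 0.000388; adjusted p = 0.177 with an estimated correlation). Also lower were 6 of 12 pericyte and smooth muscle markers (7 over the list alone, with 1 higher; camera, adjusted p = 0.000156), 10 of 23 angiogenic factors (10 over the list alone; adjusted p = 0.000424), 8 of 37 chemokines with 1 higher (10 and 1 over the list alone; adjusted p = 7.33e-05), 7 of 26 matrix protease genes with 1 higher (10 and 1 over the list alone; adjusted p = 7.33e-05) and 7 of 27 neutrophil markers with 2 higher (10 and 2 over the list alone; adjusted p = 0.000872). For these 5 lists the adjusted p with an estimated correlation was 0.306. Tslp was 3.54-fold, Plaur 4-fold and Mcam 3.68-fold lower, and the neutrophil-list gene Itgam 2.62-fold higher. Cell cycle genes were lower in 9 of 43 members and higher in 1, and in 25 and 1 over the list alone (camera, adjusted p = 2.54e-08; adjusted p = 0.422 with an estimated correlation).

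Few members of the other leukocyte lists were called between rescued and mutant corneas. Of 25 monocyte and macrophage markers, 1 was lower, Cd14 at 1.5-fold (adjusted p = 0.0257; 0.0926 without mutant replicate 1 and 0.0551 without mutant replicate 2), and none over the list alone. The median log2 difference of that list was −0.30 (camera, adjusted p = 0.00424; adjusted p = 0.504 with an estimated correlation), and its call was lost without mutant replicate 1 (adjusted p = 0.141) and without rescued replicate 3 (adjusted p = 0.101). None of 16 dendritic cell and MHC class II genes passed the test (camera, adjusted p = 0.0578). Of 25 markers of T, B, NK and mast cells, 3 were lower and 1 was higher, and 4 and 1 over the list alone (camera, adjusted p = 0.043; adjusted p = 0.504 with an estimated correlation); without mutant replicate 1, mutant replicate 3, rescued replicate 3 or WT replicate 1 the adjusted p was 0.0724, 0.103, 0.258 and 0.0524. It was 0.173 without genes below the 25th percentile of intensity, after centring on the array medians 0.0594 and with the 6 arrays of the comparison alone 0.054. Of 36 stress and cornified-type genes, 5 were higher and 8 were lower, and 5 and 12 over the list alone. The list was called downward (camera, adjusted p = 0.045, and 0.399 with an estimated correlation). Lce3a was at least 5.96-fold and Krt10 2.19-fold higher. Mean log2 intensities of Serpinb3a and S100a9 were 12.10 and 7.95 in mutant and 10.68 and 6.40 in rescued corneas. Without mutant replicate 1, mutant replicate 3 or rescued replicate 3 the adjusted p of this list was 0.0574, 0.0626 and 0.153. Without genes below the median or the 25th percentile of intensity it was 0.487 and 0.148. After centring on the array medians it was 0.0638. Of 18 conjunctiva and goblet cell markers, 3 were lower, also over the list alone, among them Krt18 at 3.24-fold and Krt8 at 2.46-fold (camera, adjusted p = 0.0149; adjusted p = 0.399 with an estimated correlation; 0.0583 without mutant replicate 2). Circadian genes were higher in 4 of 15 members and lower in 1 (5 and 1 over the list alone), with Hlf 2.11-fold higher (camera, adjusted p = 0.00572; adjusted p = 0.306 with an estimated correlation). No lens gene passed the test (adjusted p = 0.129), and 4 of 12 heat shock genes were lower, with 4 lower and 1 higher over the list alone (adjusted p = 0.103). The keratocyte, corneal endothelial, junction, growth factor, retina, skeletal muscle, gland, nerve, red blood cell and sex-linked lists had adjusted p values between 0.0947 and 0.939; among these the median and the mean differed in sign for the growth factor list (0.145 and −0.154), the muscle list, the gland list and the sex-linked list. The number of genes called between rescued and mutant depended on single arrays and was 1808 without rescued replicate 3, 1871 without mutant replicate 1 and 1931 without mutant replicate 3. An unmoderated equal-variance test per gene called 963, and an adjusted p under 0.01 left 1420. Without genes below the median intensity the T, B, NK and mast cell list turned upward (adjusted p = 0.789). The neutrophil (adjusted p = 0.288) and macrophage (adjusted p = 0.0527) lists lost their calls there too. With fry the cell cycle (adjusted p = 0.0739), macrophage (adjusted p = 0.201), T, B, NK and mast cell (adjusted p = 0.182) and stress and cornified-type (adjusted p = 0.112) lists lost theirs.

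The comparison of rescued with WT corneas asked what remained different from WT in mice with both genetic changes. Of 24 blood endothelial markers 18 were higher and 1 was lower in rescued than in WT corneas, and 18 of 25 macrophage markers and 22 of 40 actin and contractile SRF targets were higher. These 3 lists passed camera with a preset correlation and not with an estimated one (adjusted p = 0.171 with an estimated correlation, for each), and the differentiation list did not pass it (adjusted p = 0.93). Ppbp was at least 62.4-fold higher (log2 difference 5.96, SE 0.31, adjusted p = 8.57e-06), Krt17 39.5-fold higher (SE 0.12, adjusted p = 2.46e-08) and Krt16 17.4-fold higher (SE 0.15, adjusted p = 9.42e-07). Acta2 was 16.8-fold higher (SE 0.19, adjusted p = 6.01e-06). Besides Dstn, Necab1 was 12.8-fold lower (SE 0.06, adjusted p = 1.72e-09) and Enpep, the gene for glutamyl aminopeptidase, 9.34-fold lower (SE 0.09, adjusted p = 1.18e-07).

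In all, 3042 genes differed between rescued and WT corneas, 1393 higher and 1649 lower in the rescued group, and 372 of them at least 2-fold, 266 higher and 106 lower. Chil4, Alox15, Serpinb3a, Acta1, Rgs5 and Chil1 were each at least 14.1-fold higher, and Ankrd34c, Spink7, Cyp2b19 and Snx31 each at least 5.84-fold lower. Of the 40 actin and contractile SRF targets, 22 were higher than in WT and none was lower, and 25 and 0 over the list alone (camera, adjusted p = 8.63e-16; adjusted p = 0.171 with an estimated correlation), with Actg2 3.93-fold and Csrp1 3.54-fold higher. Immediate early targets were higher in 11 of 21 members and lower in 1, also over the list alone (camera, adjusted p = 4.73e-06; adjusted p = 0.188 with an estimated correlation), with Nr4a1 2.55-fold higher. Of 26 regulators of actin turnover, which include Dstn itself, 6 were higher and 3 were lower (9 and 4 over the list alone). Pfn2, the gene for profilin 2, was 1.69-fold lower. For that list camera gave an upward direction (adjusted p = 0.0336; 0.0958 without rescued replicate 2 and 0.0692 without WT replicate 3; 0.0731 with the Y-linked covariate chosen after seeing the data; adjusted p = 0.254 with an estimated correlation) and fry a downward one (adjusted p = 0.00275), and the median (0.15) and mean (−0.17) differed in sign.

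Of the 26 corneal epithelial differentiation genes, 4 were higher and 4 were lower than in WT, also over the list alone (camera, upward, adjusted p = 0.93; median −0.01, mean −0.03), with Aldh1a1 2.78-fold lower and Krt14 1.94-fold higher. Stress and cornified-type genes were higher in 11 of 36 members and lower in 6 (13 and 6 over the list alone; camera, adjusted p = 6.46e-05), with Sprr1a 7.1-fold higher. Conjunctiva and goblet cell markers were higher in 6 of 18 members and lower in 1, also over the list alone (adjusted p = 8.53e-06), with Krt8 7.74-fold and Krt18 6.16-fold higher. Monocyte and macrophage markers were higher in 18 of 25 members, and in 24 over the list alone (adjusted p = 3.19e-16), with Ly6c2 6.22-fold and Lyz2, a lysozyme gene, 3.48-fold higher. Dendritic cell and MHC class II genes were higher in 9 of 16 members (9 over the list alone, with 1 lower; adjusted p = 1.45e-05), with H2-Ab1 6.06-fold higher. Chemokines were higher in 12 of 37 members, and in 17 over the list alone (adjusted p = 1.76e-09), with Tslp at least 2.68-fold and Cxcl16 2.58-fold higher. Blood endothelial markers were higher in 18 of 24 members and lower in 1 (19 and 1 over the list alone; adjusted p = 3.48e-12), with Emcn at least 7.99-fold and Cdh5 at least 6.05-fold higher. Lymphatic markers were higher in 4 of 9 members, also over the list alone (adjusted p = 0.000101), pericyte markers in 7 of 12 with 1 lower, also over the list alone (adjusted p = 2.44e-05), and matrix protease genes in 14 of 26, with 15 over the list alone (adjusted p = 1.98e-10). Lyve1 was at least 2.12-fold, Rgs5 at least 14.9-fold and Mmp3 at least 9.6-fold higher. For these 9 lists that passed camera, the adjusted p with an estimated correlation was 0.171. Cell cycle genes were higher in 12 of 43 members and lower in 1, and in 27 and 1 over the list alone (adjusted p = 3.65e-11; adjusted p = 0.304 with an estimated correlation). Neutrophil markers were higher in 6 of 27 members, also over the list alone (adjusted p = 5.43e-05; adjusted p = 0.186 with an estimated correlation), and T, B, NK and mast cell markers in 5 of 25 with 1 lower, and in 9 with 1 lower over the list alone (adjusted p = 0.000212; adjusted p = 0.256 with an estimated correlation). Interferon response genes were higher in 5 of 21 members, and in 6 over the list alone (adjusted p = 1.89e-05; adjusted p = 0.344 with an estimated correlation). For this list the difference among the rescued pools given above applies here too.

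Lens genes were lower than in WT in 13 of 18 members, and in 14 over the list alone (camera, adjusted p = 6.22e-10; adjusted p = 0.171 with an estimated correlation). The median log2 difference of the list was −0.75. Crygs was 7.4-fold, Cryba1 6.59-fold and Cryaa 5.52-fold lower, and the mean log2 intensity of these 3 genes was 8.18 to 9.0 in the 3 rescued pools. Circadian genes were lower in 9 of 15 members and higher in 2, and in 9 and 3 over the list alone (adjusted p = 0.00289; adjusted p = 0.188 with an estimated correlation), with Nr1d1 2.21-fold and Dbp 1.83-fold lower. Corneal endothelial genes were lower in 2 of 11 members and higher in 1, and in 3 and 1 over the list alone (adjusted p = 0.0493; adjusted p = 0.305 with an estimated correlation), and retina and pigment cell genes were lower in 1 of 13, and in none over the list alone (adjusted p = 0.0472; adjusted p = 0.188 with an estimated correlation). The endothelial call was lost without mutant replicate 3 (adjusted p = 0.0608), rescued replicate 2 (0.0588), rescued replicate 3 (0.124) or WT replicate 2 (0.111), and the retina call without rescued replicate 1 (0.109), rescued replicate 3 (0.0552) or WT replicate 3 (0.0772). Without genes below the 25th percentile of intensity their adjusted p was 0.0745 and 0.119, and with array weights 0.051 and 0.052. The retina list had 0.331 without genes below the median intensity. The endothelial list had 0.0507 with the mean of all rows of a gene and 0.0543 with the 6 arrays alone. The angiogenic, keratocyte, junction, growth factor, muscle, gland, nerve, heat shock, red blood cell and sex-linked lists had adjusted p values between 0.0596 and 0.841, with 4 of 23 angiogenic factor genes higher, among them Vegfa at 1.67-fold; the median and the mean of the growth factor list differed in sign (−0.07 and 0.15). The number of genes called between rescued and WT was 1812 without rescued replicate 2, an unmoderated equal-variance test per gene called 771, and an adjusted p under 0.01 left 1374. The T, B, NK and mast cell list lost its call without genes below the median intensity (adjusted p = 0.197), and the interferon list with fry (adjusted p = 0.112). Higher genes were 45.8% of all calls (51.8% after quantile normalisation and 47.0% after centring on the array medians) and 71.5% of the calls of at least 2-fold.

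**Figure D2:**
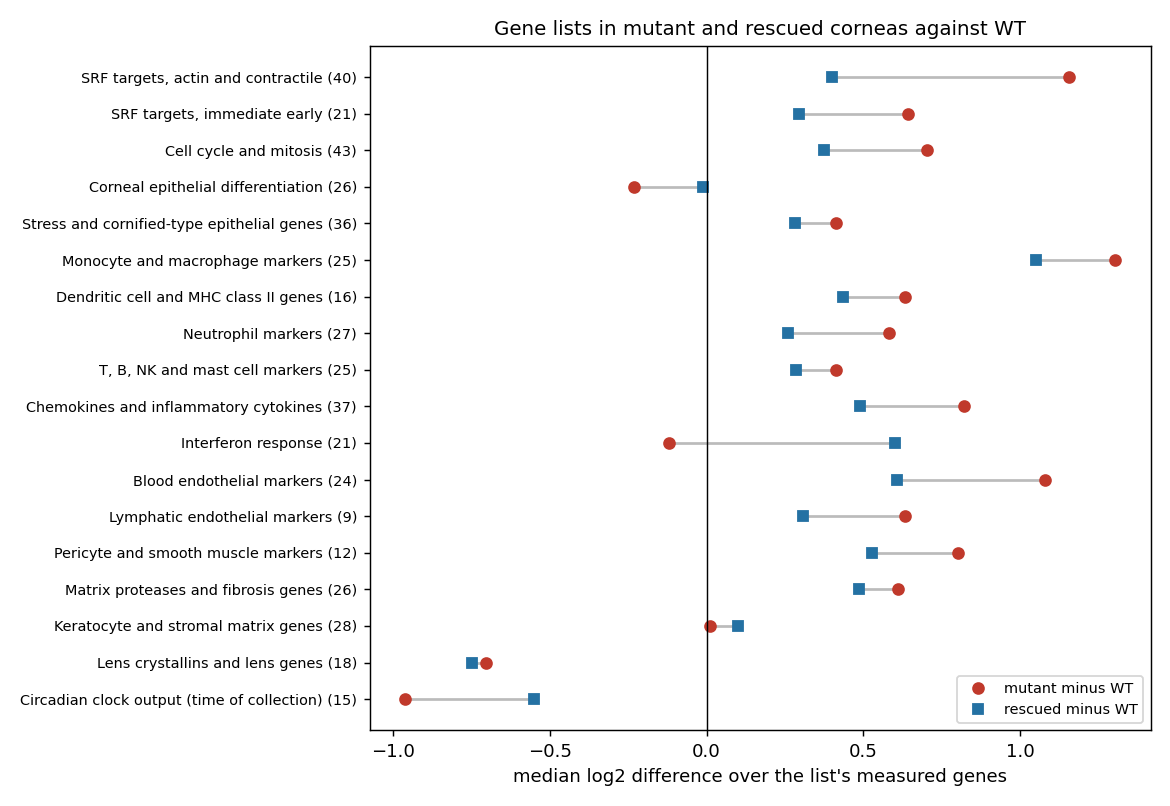
Median log2 difference from WT (horizontal axis) over the measured genes of 18 gene lists (number of genes in parentheses), for mutant minus WT (circles) and rescued minus WT (squares), each over 3 arrays per group. The contractile SRF targets lay at 1.16 in mutant and 0.40 in rescued corneas, the monocyte and macrophage markers at 1.30 and 1.05, and the epithelial differentiation genes at −0.23 and −0.01.

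The overlap of the first pair of comparisons gives the extent to which mutant values lay closer to WT in the rescued corneas. Of the 7004 genes called between mutant and WT, 2617 were called in the opposite direction between rescued and mutant, 1357 that were higher and 1260 that were lower in the mutant. Another 15 were called further from WT. Independent lists of these sizes would share 466.6 genes. In 100 simulations without any group effect, with the mutant arrays shared, at most 1 gene overlapped. Such data yield almost no calls, so that count was fixed in advance and does not measure the effect of the shared arrays. Part of the excess may come from the shared mutant arrays, since 3 arrays cannot be split into groups of at least 2. The covariance of the log2 differences across genes was −0.121, against −0.00617 in the simulations. Over all 7004 genes the median share of the mutant change that was reversed was 49.3%, against a highest value of 3.93% in 100 simulations in which rescued equalled mutant. The median share was 52.5% for genes higher and 46.0% for genes lower in the mutant. The order was the opposite for changes of at least 2-fold (46.0% for 674 higher and 52.5% for 442 lower genes). In the 3 rescued pools it was 47.5%, 41.6% and 60.5%. By list, over the members called between mutant and WT, the median share was 90.6% for corneal epithelial differentiation genes, 61.2% for contractile SRF targets, 49.8% for cell cycle genes, 42.2% for blood endothelial markers, 33.9% for stress and cornified-type genes and 26.9% for monocyte and macrophage markers. On the linear scale the macrophage share was 27.2%, 17.5% and 63.7% in the 3 rescued pools and the differentiation share 78.2%, 75.7% and 91.8%. The bootstrap 95% interval of their difference was 14.9 to 73.7 percentage points in rescued replicate 1 and 20.4 to 83.1 in rescued replicate 2. It included 0 in rescued replicate 3 (−3.07 to 49.1 percentage points). These intervals resample the genes of a list as if they were independent and do not measure the spread among pools. The median share was 135.5% over only 6 called members of the 21 interferon response genes, a list in which rescued replicate 3 stood apart (departure 0.06, against 0.92 and 0.94), so that a return beyond WT was not shown for every pool. For the lens genes it was −30.4% over 11 called members of 18, but none of the 18 was called between rescued and mutant (camera, adjusted p = 0.129). The mean log2 intensity of Cryaa, Cryba1 and Crygs overlapped, at 8.18 to 9.0 in the rescued and 8.54 to 10.4 in the mutant pools. A move further from WT than in the mutant was therefore not shown. Against a uniform return of all genes, no list passed camera with an estimated correlation (lowest adjusted p = 0.0599).

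By class, 1561 genes (22.3%) were called opposite between rescued and mutant and not called between rescued and WT. Another 1027 (14.7%) were called opposite and still called against WT, and 29 were called beyond WT. A further 1649 (23.5%) were not called between rescued and mutant and still called against WT, and 2723 (38.9%) were called in neither comparison of the rescued group. The count of opposite calls was 1642 without rescued replicate 3 and 1702 without mutant replicate 1.

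**Figure D3:**
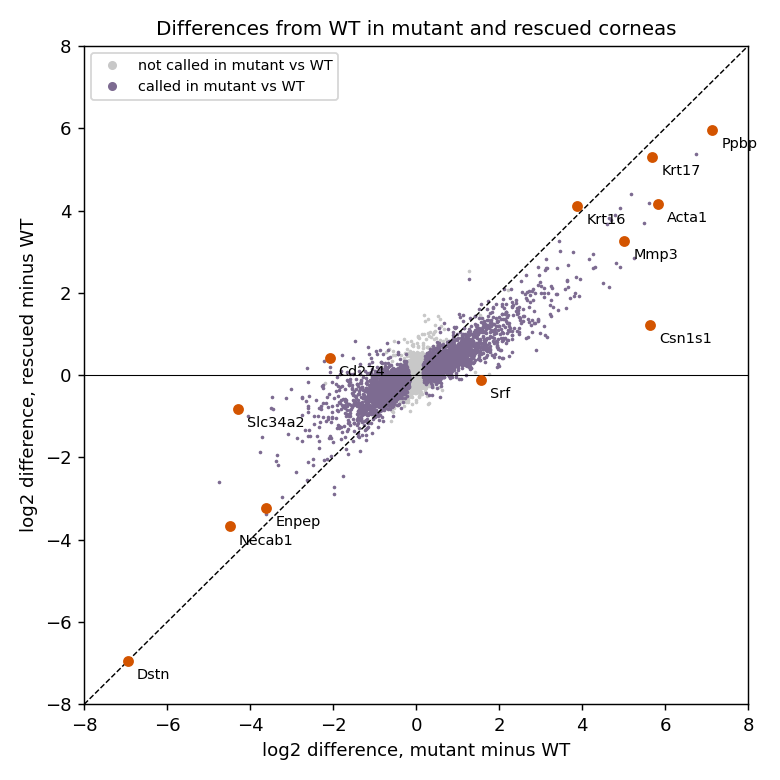
Log2 difference from WT in rescued corneas (vertical axis) against that in mutant corneas (horizontal axis) for the 22180 genes tested, with the 7004 genes called between mutant and WT in purple and 12 named genes in orange. Points on the dashed line have equal differences in both groups, as Dstn at −6.95 and −6.96, and points near the horizontal line lie near WT in rescued corneas, as Srf at −0.12.

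Genes that stood apart in the rescued corneas from both other groups were fewer. In the same direction against mutant and against WT, 153 genes were called, 96 higher and 57 lower in the rescued group. Independent lists would share 203.5. Simulations without a group effect gave none, but such data yield almost no calls, so that outcome was fixed in advance. Of the 153 genes, 109 were not called between mutant and WT. Examples chosen after their values were seen are Slc5a1, the gene for the sodium-glucose cotransporter SGLT1, 2.04-fold higher than in mutant and 1.74-fold higher than in WT (adjusted p = 0.00166 and 0.00657), and Adamtsl4, 1.92-fold and 1.77-fold higher (adjusted p = 0.00157 and 0.00358). Cdkn2b, a cell cycle inhibitor gene, was 1.56-fold and 1.45-fold higher (adjusted p = 0.00296 and 0.00766). Cdr2 was 1.63-fold lower than in mutant and 1.82-fold lower than in WT (adjusted p = 0.00124 and 0.000517), and Bmp7, the gene for a bone morphogenetic protein, 1.51-fold and 1.44-fold lower (adjusted p = 0.000536 and 0.00123). The count of 153 fell to 91 without rescued replicate 2 or without WT replicate 1, 97 without WT replicate 2 and 100 without mutant replicate 3. It was 27 with the unmoderated test, 33 at an adjusted p under 0.01, 257 without genes below the median intensity, 230 with the trend and robust options of limma, 94 over all rows of the table and 89 with Y-linked expression as a covariate, an alternative chosen after seeing the data.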

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

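The tests of the Cre signal were chosen only after the result was seen.

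The arrays carry control probe sets for the Cre recombinase of bacteriophage P1, which serve a hybridisation spike-in on 1 strand and can report Cre mRNA on the other. On the mRNA strand, the mean of 4 probe sets was 7.86 ± 0.57 (SD, n = 3) on the rescued arrays and 6.15 ± 0.06 (SD, n = 6) on the others, a signal outside the measurement used for the comparisons. The difference was 1.72 on the log2 scale, or at least 3.29-fold, and between 1.37 and 2.05 for single probe sets (exact permutation test of the mean, two-sided p = 0.0119, the smallest that the 84 splits of 9 arrays can give). Unequal amounts of spike-in are excluded by the probe sets for the spike-in strand, whose largest difference was 0.0583. Brighter nonspecific signal on the rescued arrays is excluded by 41 other bacterial mRNA-strand probe sets, whose median difference was −0.120. All 4 mRNA-strand probe sets separated the 3 rescued arrays from the 6 others, which is consistent with Cre transcripts from a transgene in the rescued mice. That remains a hypothesis, found and tested on the same arrays. The genotype of the other groups at such a transgene is not given in the sources used here. If they lack it, effects of the transgene cannot be told apart from those of Srf ablation in either comparison of the rescued group.

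Among 17634 array features that name no single gene, and so stand outside the comparisons, 762 were called higher and 1347 lower in mutant than in WT corneas in a limma fit. Between rescued and mutant 276 were higher and 234 lower, and between rescued and WT 167 were higher and 269 lower.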

How the results depend on the processing

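The covariate for Y-linked expression was chosen only after the result was seen. Over all alternatives, named genes stayed on their side of the threshold in 13295 cases and gained a call in 131. They lost a call in 848 and reversed in 0. For gene lists these counts were 1718, 36, 100 and 3. A reversal was counted only where a result was called in the main fit or in the alternative. Some alternatives, such as the stricter threshold, kept the fold changes of genes, so no reversal was possible there. Of the lost list calls, 58 came with an estimated correlation. The counts of genes called between mutant and WT, rescued and mutant, and rescued and WT were 7070, 3075 and 3062 after quantile normalisation. With the replicate number as a block they were 6687, 2507 and 2656, and with the Y-linked covariate 6140, 2765 and 2185. The median share reversed lay between 44.1% without rescued replicate 3 and 54.1% without rescued replicate 2.

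The unmoderated equal-variance test per gene called 963 genes between rescued and mutant and 771 between rescued and WT, with 841 opposite calls and 27 genes apart in the rescued group. An adjusted p under 0.01 gave 1420 and 1374, with 4165 in the F test, 1310 opposite calls and 33 apart. A 2-fold minimum gave 1116, 312 and 372 for the 3 comparisons, 282 opposite calls and 2 apart; fewer genes pass both limits by construction. The number apart was 257 without genes below the median intensity, 94 over all table rows, 230 with trend and robust options and 89 with the Y-linked covariate. The T, B, NK and mast cell list turned upward between rescued and mutant without genes below the median intensity (adjusted p = 0.789). The actin turnover list turned downward with fry, against WT, in mutant (adjusted p = 0.0913) and rescued (adjusted p = 0.00275) corneas. That list holds Dstn, the mutated gene, at mean log2 intensities of 12.57 in WT, 5.63 in mutant and 5.62 in rescued corneas. The list was not tested without Dstn, so the downward direction cannot be credited to its other members. Apart from the 2-fold minimum, the cause was not tested.

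With 1 array left out, the counts were 5913 to 6948 between mutant and WT, 1808 (without rescued replicate 3) to 2795 between rescued and mutant, 1812 (without rescued replicate 2) to 2975 between rescued and WT and 5297 to 6219 in the F test. Opposite calls were 1642 to 2429, and genes apart 91 to 130. Signal over background limits dim genes, and 3 arrays per group limit changes near 0.5 on the log2 scale. In simulated data with far fewer changed genes than were called here, 70% of such changes were recovered, so recovery in these comparisons may differ.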

Other observations

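The tests of the partial return and of the lists off the general return were chosen only after the result was seen; the splits and the tests near Dstn were not.

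Of the 10 splits of the 6 arrays of a comparison into 3 and 3, with the other group kept in the fit, 1, the real split, gave as many genes in each comparison. The real counts were 7004, 2959 and 3042 and the highest other count was 0 in each, and 10 splits are too few for a share under 0.05. For the F test, 1 of 100 drawn splits of the 9 arrays into 3 groups of 3, the real one, gave as many genes as the real 6524, and the highest other gave 2628, so chance can be excluded there.

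The mutant changes were reversed in part in the rescued pools. Chance values of the shared mutant arrays are excluded as the whole cause, since the median share reversed was 49.35% and at most 3.93% in simulations without return. WT corneas mixed into the rescued pools are excluded by Dstn, whose rescued minus mutant difference was −0.0093 on the log2 scale (SE 0.08), where pools with equal parts of WT and mutant corneas would give 5.96. A mix of corneas wholly at the WT level and corneas wholly at the mutant level could give partial values, with 1 linear-scale share for all genes. The share that suited each rescued pool best was 48%, 45% and 70%. Of 6778, 6835 and 6948 genes, 28, 43 and 126 lay off it between the mutant and WT means (adjusted p under 0.05). Some of them were closer to mutant and some closer to WT. Each held-out mutant or WT array gave 0, but at best shares of 0% and 97%, where the predicted values lie near a group mean. These arrays do not show how many genes would lie off a middle share by chance. That test therefore cannot exclude such a mix. Among the 10 largest decreases in the mutant, returns were unlike. Mean log2 intensities in WT, mutant and rescued corneas were 11.06, 6.56 and 7.38 for Necab1 and 10.30, 6.69 and 7.07 for Enpep. For Slc34a2 they were 11.82, 7.52 and 11.01, and for Ly6g6c 13.1, 9.62 and 12.58 (SEs of the mutant minus WT differences 0.06 to 0.10). For these genes the values argue against a mix alone, but a mix beside a partial return within corneas stays open.

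Around Dstn on chromosome 2, 7 of 100 neighbouring genes were called alike against WT in mutant and rescued corneas and not called between them. Tmem230, Snap25, Dzank1, Dtd1, Kiz and Napb were lower and Cst3 was higher. Chance clustering could account for this, as 58.42% of 1996 other windows of 100 genes, which overlap one another, held as many. Alleles linked to the Dstn mutation cannot be told apart from it, since the count of 7 equals the median window. Probes that mismatch a linked haplotype would lower the signal, and 85.71% of the 7 genes were lower (exact 95% interval 42.1 to 99.6), against 59.3% elsewhere, too few genes to decide. These genes were named after their values were seen.

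A hypothesis was that some gene lists may lie off the general relation between the mutant change and the return. With camera at the preset correlation, 6 lists passed an adjusted p of 0.05 against a uniform return of all changed genes. Each had 1 direction in all 3 rescued pools. None passed camera with an estimated correlation (lowest adjusted p = 0.0599), so a departure was not shown. The estimated correlation was 0.719 for the interferon, 0.462 for the lens, 0.420 for the blood endothelial and 0.164 for the dendritic cell list. Their departures cannot be told apart from shared variation of the listed genes. For the differentiation and nerve lists it was 0.00936 and 0.00334, below the preset 0.01. Shared variation is therefore not the reason that those lists did not pass. Among these 6 lists the largest departures were in the interferon list (median 0.64, with 0.92, 0.94 and 0.06 in the 3 pools) and the lens list (median −0.42).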
